A study of Mus musculus with 6 samples.

How the data were processed

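Auditory nerves were microdissected from the cochleae of young adult mice, per the labels' protocols. RNA from both cochleae of a mouse was pooled, total RNA was purified with a column kit, samples of low quality on a Bioanalyzer were left out, and libraries were made with a TruSeq RNA kit. Whether the libraries kept strand, the read length and the aligner are not given in the sources used here, nor is how reads that match more than 1 gene were counted. The groups were 3 wildtype and 3 Vcan knockout samples, taken from the genotype in the labels.

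A single deposited table holds 24067 rows, each with a gene symbol and, for all but 272 symbols, a gene identifier. Per the submitters' processing notes, reads were mapped to mm10, counted per gene with HTSeq and compared with DESeq2, with no versions given. The per-sample values are raw counts made by the authors, whole numbers whose totals differ between libraries, and were not normalised. The same table holds the authors' own comparison: per the file headers, a mean of normalised counts for each gene (a signal averaged over all samples), a log2 fold change with its standard error, a test statistic (a score, per the file headers), a p-value and an adjusted p-value, all made by the authors and deposited as such. The authors' values were used only where the text names their table, and no test was run on them. The authors' log2 fold changes are on a scale of their own (−0.87 against −1.20 here for Vcan), so the 2 are not set side by side otherwise.

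There were 5 symbols listed on 2 rows with identical counts, which were joined, leaving 24062 symbols, of which 3878 had 0 counts in all libraries. The table holds no genes encoded by mitochondrial DNA under the symbols listed, so that list was not tested. Coordinates come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 is made from, by gene identifier. They were found for 23711 symbols. Library totals were 74530860 to 92513887 counts. Intervals on counts cover counting error only, since reads without molecular identifiers are not independent molecules.

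Differential expression was tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (16722 genes), libraries were scaled by TMM (factors 0.964 to 1.02), and robust quasi-likelihood F tests (2-sided) of knockout against wildtype were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. No covariate or block was used. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are TMM-scaled, and errors on them are SDs over the 3 libraries of a group. The ratio for Gbp2b, which had 3 counts over all wildtype libraries, was computed from summed counts with an exact binomial interval. The pipeline was tested on counts simulated from these libraries, 16722 genes with about 50 genes changed at each of 4 fold sizes. There edgeR recovered 18%, 77.6%, 90% and 94% of genes changed 2, 4, 8 and 16-fold with 9.74% false calls, and DESeq2 recovered 46%, 92%, 100% and 96% with 32.4% false calls. With no gene changed, edgeR made 0 calls. Each gene was drawn independently with the dispersion that edgeR estimated, so differences shared by many genes of a library were left out. In the real counts another split of the samples gave 915 edgeR calls, so these rates need not hold there.

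Before the data were examined, 42 gene lists were written for the nodes of Ranvier, the matrix around them, the glia and neurons of the nerve, other cochlear, bone, marrow and immune cells that a dissected nerve could hold, and stress, metabolic, clock and sex-linked genes. The 41 lists with at least 5 measured genes were tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, 2-sided, adjusted over the lists, and again with an estimated correlation and with fry. Older symbols used in the table were matched by hand for 6 genes. Members were also counted after adjustment over the list alone. Genes were named by a rule fixed at the same time: Vcan, then of the genes past the threshold with no overlap between the groups and a mean of at least 2 CPM, leaving out predicted genes, pseudogenes and antigen receptor segments, the 10 highest and 10 lowest fold changes or all if fewer, which gave 8 and 7, not all of which are described. From each list came up to 4 members past the threshold or, where none passed, up to 2 members of the highest mean, given as values, and any member of the node and matrix lists. Members named for passing over the list alone, and a few others the text names as such, were chosen after their values were seen.

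Libraries were compared before averaging. No pair agreed within sampling noise (the lowest chi-square per degree of freedom was 41.7), so all 6 were counted. Sharing of sequence between genes was measured as the percentage of 50-base stretches in the longest GENCODE vM21 transcript of a gene that occur in a gene at another locus.

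The alternatives tried were other scalings (DESeq2 size factors, upper quartile, library size alone, scaling without blood cell genes), no filter or a stricter filter (1 CPM in 3 libraries), the replicate number as a block, leaving out each library, limma-voom, DESeq2 1.42.0, other thresholds and other list tests. After seeing the data, an offset for transcript length, a block for the transcript-length trend, and 1 or 2 surrogate variables (sva 3.50.0) were added.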

Results

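Gene expression was measured by RNA sequencing in the auditory nerve of young adult mice, the tract of spiral ganglion neuron axons and their glia that carries signals from the cochlea to the brainstem. The comparison asked how the nerve's transcripts differ between wildtype C57BL/6 mice and mice deficient in versican, a large chondroitin sulfate proteoglycan of the extracellular matrix that is encoded by Vcan. The labels give the wildtype strain as C57BL/6, and the submitters' design text names the wildtype mice C57BL/6J. There were 3 wildtype and 3 knockout libraries. Each held RNA from the nerves of both cochleae of a single mouse. The spread between libraries thus joined differences between animals with those of dissection and library preparation, which cannot be told apart here. Wildtype replicate 3 correlated with the other libraries at 0.9475 to 0.9566 (log2 CPM), lower than any other pair. The wildtype libraries held 82860217, 88543242 and 88694031 gene counts and the knockout libraries 74530860, 92513887 and 86179835. Ptgds, a prostaglandin D synthase, took the largest share of counts (1.17% to 2.23%) in every library except knockout replicate 3, in which Coch, a cochlear matrix protein, took 1.42%.

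Vcan itself (gene identifier 13003, chromosome 13, 89655309 to 89743027, GRCm38) was counted at 8.43 ± 1.15 CPM (counts scaled to library size; SD, n = 3) in wildtype nerve and at 3.67 ± 1.54 (SD, n = 3) in knockout nerve. All 3 knockout libraries, with 413, 249 and 248 counts, lay below all 3 wildtype libraries, with 697, 864 and 626. The log2 fold change was −1.20 (SE 0.32), and the difference did not pass correction over the 16722 genes tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.558; unadjusted p = 0.00815). It passed in DESeq2 (adjusted p = 0.0342) and in the authors' deposited table, also made with DESeq2 (adjusted p = 0.0348 at a log2 fold change of −0.87). The labels do not say which part of the gene was altered, and counts over a whole gene do not tell a shortened transcript from an intact one.

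Few genes separated the genotypes beyond the spread between libraries. Of the 16722 genes tested, 23 differed at an adjusted p under 0.05 (edgeR), 11 higher and 12 lower in knockout nerve, and all 23 differed at least 2-fold with no overlap between the groups. At an unadjusted p under 0.05 there were 870 genes, while other splits of the 6 libraries into 3 and 3 gave 74 to 4314. The groups did not overlap for 10.3% of genes, against 10% by chance for 3 libraries against 3. DESeq2 called 252 genes, 121 higher and 131 lower, and the authors' deposited table holds 228 genes at an adjusted p under 0.05, 107 higher and 121 lower. All 23 genes were among the calls of both, in the same direction as in the authors' table. The authors' comparison was also made with DESeq2 on these counts, so the 2 are not separate evidence. The 22 that could be placed lay on 13 chromosomes. None lay within 20 Mb of Vcan, where 179 genes were tested, and 4 of the 248 placed DESeq2 calls did. The number of calls depended on each animal: 7, 3 and 7 genes passed without wildtype replicates 1, 2 and 3, and 14, 3 and 5 without knockout replicates 1, 2 and 3. Of the 23 genes, Eno1b and Gbp2b alone passed in all 6 of these fits. The log2 fold changes moved less, over 19 alternatives that include these fits from −1.73 to −1.64 for Cd59a, from 1.22 to 1.32 for Nnt and from −1.63 to −1.48 for Acp1. The ranges were wider for Gbp2b (9.29 to 10.62), Pttg1 (−6.26 to −5.47) and Mc4r (3.83 to 4.54). In counts simulated from these libraries edgeR recovered 18% of genes changed 2-fold and 77.6% of those changed 4-fold, so a smaller change was often not detectable with 3 animals per group.

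Among the genes higher in knockout nerve, the largest fold change belonged to Gbp2b, a guanylate-binding protein of the interferon-inducible GTPases (chromosome 3, 142594816 to 142619179), with 3 counts over the wildtype libraries and 2958 over the knockout libraries. The ratio of normalised counts was 1003 (95% exact interval 343 to 4865, for counting error only; edgeR adjusted p = 0.00695). Eno1b, an enolase gene on chromosome 18 (48045335 to 48048379), was at 0.334 ± 0.081 CPM in wildtype and 118 ± 26.6 CPM in knockout nerve (SD, n = 3; log2 fold change 8.45, SE 0.32, edgeR adjusted p = 0.000718). Its value is uncertain, because 84.5% of its 50-base stretches also occur in a gene at another locus, and Eno1, the enolase gene it resembles, was counted at only 0.139 CPM in wildtype nerve. Serpina3n, a serine protease inhibitor, rose from 3.06 ± 1.15 to 30.1 ± 5.33 CPM (SD, n = 3; log2 fold change 3.29, SE 0.31, edgeR adjusted p = 0.0208). Mc4r, a melanocortin receptor, rose by 4.16 (SE 0.47) on the log2 scale and Pla2g4e, a cytosolic phospholipase A2, by 2.66 (SE 0.26). Slc6a4, the serotonin transporter, rose by 2.47 (SE 0.28) and the long noncoding transcript AA465934 by 3.25 (SE 0.24). The smallest of these increases was that of Nnt, the nicotinamide nucleotide transhydrogenase of the inner mitochondrial membrane (chromosome 13, 119335527 to 119409257), which was at 32.7 ± 0.372 CPM in wildtype and 79.1 ± 6.05 CPM in knockout nerve (SD, n = 3; log2 fold change 1.28, SE 0.12, edgeR adjusted p = 0.0208). C57BL/6J, the strain named for the wildtype mice, is known to carry a multi-exon deletion in Nnt. The Nnt difference therefore need not follow from versican deficiency.

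Among the genes lower in knockout nerve, Pttg1, which encodes the mitotic regulator securin (chromosome 11, 43420244 to 43427463), fell from 45.0 ± 5.8 to 0.865 ± 0.481 CPM (SD, n = 3; log2 fold change −5.69, SE 0.43, edgeR adjusted p = 0.00874). The vomeronasal receptor gene Vmn2r29 was at 4.65 ± 0.41 CPM in wildtype and 0.0759 ± 0.0295 CPM in knockout nerve (SD, n = 3; log2 fold change −5.92, SE 0.39). Cd59a, an inhibitor of the complement membrane attack complex, fell from 105 ± 6.44 to 32.8 ± 1.24 CPM (SD, n = 3; log2 fold change −1.68, SE 0.12, edgeR adjusted p = 0.00806). The log2 fold change was −2.81 (SE 0.21) for Rpl29, a protein of the large ribosomal subunit, and −1.56 (SE 0.14) for the phosphatase Acp1. It was −1.51 (SE 0.14) for the tyrosine phosphatase Ptpn3. Vmn2r29, Rpl29 and Acp1 shared 22.3%, 47.9% and 13.1% of their 50-base stretches with genes at other loci. How reads that match several genes were counted is not given, so the CPM values of such genes are uncertain. Cd59a shared 3.98%, and its paralog Cd59b was also lower, at 3.11 ± 1.17 CPM in wildtype and 0.824 ± 0.216 CPM in knockout nerve (SD, n = 3), past the threshold in DESeq2 and not in edgeR. The 23 genes also held 6 predicted genes or pseudogenes and the low-count genes Drd1a and Slfn8, and not every gene that passed is described.

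**Figure D1:**
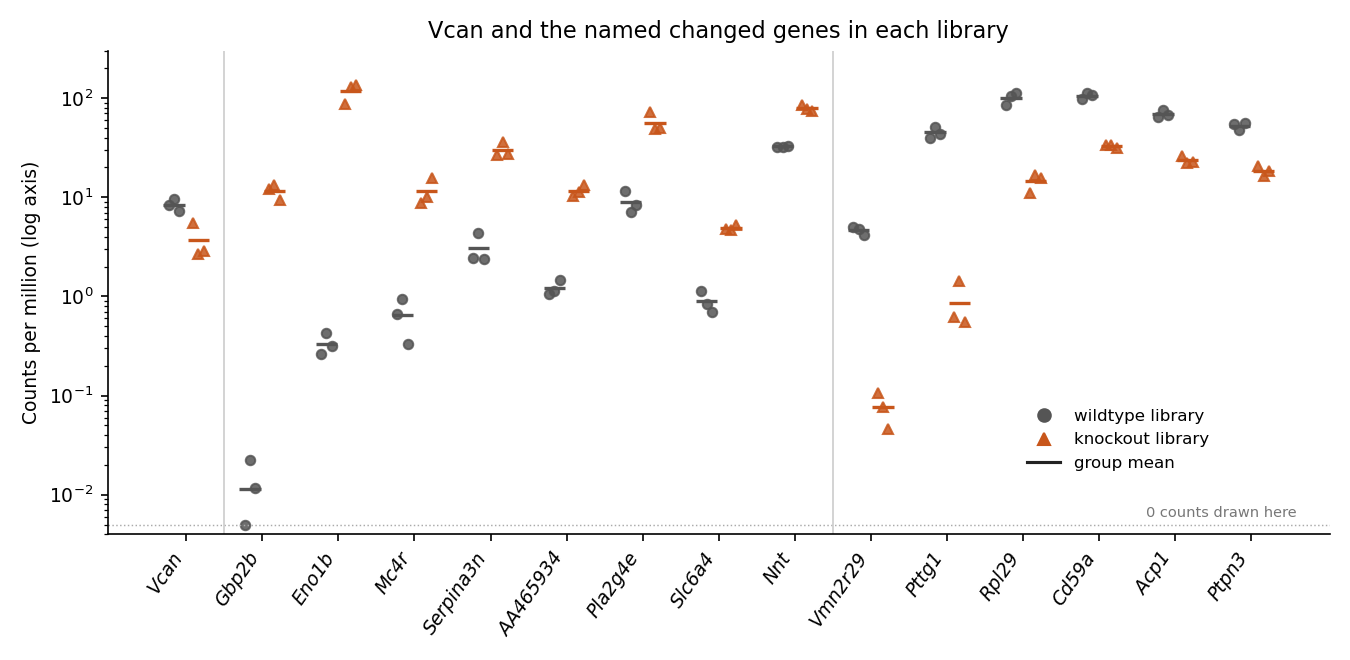
CPM (log axis) of Vcan, of the genes described as higher and of those described as lower in knockout nerve, with a circle for each wildtype library, a triangle for each knockout library and a bar for each group mean. The groups do not overlap for any of the genes shown, and the knockout mean of Vcan is 3.67 CPM against 8.43 CPM in wildtype.

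Versican contributes to the matrix around the nodes of Ranvier, the gaps in the myelin at which sodium channels cluster. Transcripts of nodal, paranodal and juxtaparanodal proteins did not differ detectably as a group. None of the 30 genes of this list passed, over all genes or when adjusted over the list alone (edgeR), and the median log2 fold change was 0.08 (camera with a preset correlation of 0.01, adjusted p = 0.309). The adhesion molecule Cntn1 was at 253 ± 66.7 CPM in wildtype and 380 ± 42.6 CPM in knockout nerve, gliomedin (Gldn) at 148 ± 42.8 and 208 ± 13.5, and the sodium channel Scn8a at 293 ± 131 and 329 ± 52.0 (SD, n = 3). Neurofascin (Nfasc) was at 424 ± 142 and 404 ± 119 CPM (SD, n = 3). This list passed in 2 of the fits that left out an animal, without wildtype replicate 1 (mean log2 fold change 0.31, adjusted p = 0.000736) and without knockout replicate 2 (0.17, adjusted p = 0.0458), and its mean turned to −0.18 without knockout replicate 1.

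The partners of versican in the perinodal and perineuronal matrix did not change as a group either. Of 23 genes, 8 were higher and 15 lower in knockout nerve, with a median log2 fold change of −0.16 (camera, adjusted p = 0.452), and none passed over all genes. The list was called without wildtype replicate 3 (mean log2 fold change −0.15, adjusted p = 0.0438, against −0.09 with all libraries). Its mean was −0.22 without knockout replicate 1 and 0.01 without wildtype replicate 1, neither of which passed. Adjusted over the list alone 1 gene passed, the matrix glycoprotein Fbln2, at 45.3 ± 4.04 CPM in wildtype and 72.6 ± 4.13 CPM in knockout nerve (SD, n = 3; log2 fold change 0.68, SE 0.13, edgeR adjusted p = 0.0275 over the list alone and 0.247 over all genes). Fbln2 was also the only gene of this list under 0.05 in the authors' deposited table. Other proteoglycans and their link proteins did not pass. Brevican (Bcan) was at 156 ± 65.7 and 169 ± 11.2 CPM, Acan, the aggrecan gene, at 148 ± 24.5 and 110 ± 19.5, Ncan, the neurocan gene, at 18.5 ± 8.14 and 15.1 ± 2.21, and Hapln2, a link protein of central nodes, at 35.9 ± 16.4 and 18.9 ± 3.49 (wildtype and knockout, SD, n = 3). Tenascin R (Tnr) was at 4.92 ± 3.02 CPM in wildtype and 5.33 ± 4.21 CPM in knockout nerve (SD, n = 3).

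Of the 41 gene lists tested, 10 were called with the preset correlation, 8 lower and 2 higher in knockout nerve. None of the 10 kept its call with an estimated correlation or with fry, which tests whether the genes of a list move on balance one way. The estimated correlation was 0.41 for the astrocyte, 0.59 for the oligodendrocyte, 0.34 for the interferon and 0.02 for the clock list. Of the 10 splits of the 6 samples into 3 and 3, 9, counting the real one, gave at least 10 called lists, up to 18. A call with the preset correlation therefore does not by itself tell genotype from other differences between libraries. No member of a called list passed over all genes in edgeR. The members named here and below because they passed over the list alone, and Npas2, Clock, Xist, Eno1 and Cd59b, were chosen after their values were seen.

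The lists written for central glia were lower in knockout nerve with the preset correlation. Which cells of the dissected pieces the transcripts came from was not measured. All 15 astrocyte genes had a negative fold change, with a median of −0.71 on the log2 scale (camera, adjusted p = 5.4e-07; adjusted p = 0.747 with an estimated correlation and 0.516 with fry). Adjusted over the list alone 2 passed, the water channel Aqp4 (194 ± 80.2 to 68.9 ± 17.0 CPM, SD, n = 3; edgeR adjusted p = 0.0405 over the list alone and 0.381 over all genes) and Cldn10 (6.08 ± 1.69 to 2.87 ± 0.0764 CPM, SD, n = 3; edgeR adjusted p = 0.0405 and 0.447). Gfap, the astrocyte intermediate filament, was at 371 ± 138 CPM in wildtype and 223 ± 69.5 CPM in knockout nerve (SD, n = 3). Of the 19 oligodendrocyte genes 17 were lower, with a median of −0.65 (camera, adjusted p = 0.000193; adjusted p = 0.926 with an estimated correlation). Enpp6, a marker of newly formed oligodendrocytes, passed over the list alone (18.1 ± 1.28 to 10.05 ± 0.88 CPM, SD, n = 3; edgeR adjusted p = 0.0191, and 0.227 over all genes), while transferrin (Trf) was at 2205 ± 930 and 2420 ± 442 CPM. Relative to the wildtype mean, the median of the astrocyte list was 0.50 in wildtype replicate 2 and −0.65 in wildtype replicate 3, and between −1.01 and −0.48 in the knockout libraries. The oligodendrocyte call was lost without wildtype replicate 2 (mean log2 fold change −0.21, adjusted p = 0.0841) and without knockout replicate 1 (−0.43, adjusted p = 0.104), against −0.58 with all libraries, while the astrocyte call was kept without each library in turn.

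Lists for peripheral myelin and for the neurons were not called with all libraries, and each was called without 1 of them. The Schwann cell myelin list had a median log2 fold change of −0.05 (23 genes, camera, adjusted p = 0.577). Without wildtype replicate 3 its mean was −0.21 (adjusted p = 0.00528) against −0.09. The spiral ganglion neuron list had a median of 0.11 (30 genes, adjusted p = 0.209), with Snap25 at 2683 ± 1004 and 3224 ± 356 CPM (SD, n = 3). The median of the voltage-gated potassium channel list was 0.08 (23 genes, adjusted p = 0.577). Without wildtype replicate 1 the means of the neuron and channel lists were 0.23 (adjusted p = 0.00505) and 0.60 (adjusted p = 0.00443), against 0.06 and 0.01. Relative to the wildtype mean, wildtype replicate 3 stood at −0.48 on the neuron list, below the 5 other libraries. The median was 0.05 for the list of satellite and nonmyelinating glia (18 genes, adjusted p = 0.771).

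Transcripts induced by type I interferon were lower in knockout nerve, with 19 of 20 genes down and a median log2 fold change of −0.59 (camera, adjusted p = 5.4e-07; adjusted p = 0.747 with an estimated correlation and 0.516 with fry). Adjusted over the list alone 4 genes passed. Oasl2 (22.9 ± 3.69 to 9.74 ± 1.91 CPM), Ifit3 (34.4 ± 7.06 to 18.1 ± 3.17 CPM) and Oas1a (2.98 ± 0.578 to 1.24 ± 0.415 CPM) were lower (SD, n = 3; edgeR adjusted p = 0.00725, 0.0236 and 0.0479 over the list alone). Xaf1, a proapoptotic gene of the same list, went the other way, from 9.98 ± 2.28 to 28.0 ± 3.13 CPM (SD, n = 3; edgeR adjusted p = 0.00482 over the list alone and 0.0984 over all genes). Ifit1 was at 34.2 ± 1.36 and 33.7 ± 3.99 CPM (SD, n = 3). The macrophage and microglia list was lower too, with 18 of 25 genes down and a median of −0.255 (camera, adjusted p = 0.00133; adjusted p = 0.926 with an estimated correlation), and none of its genes passed over the list alone. Relative to the wildtype mean, its median was −0.29 and −0.39 in knockout replicates 1 and 3, and 0.04 in knockout replicate 2, above the 3 wildtype libraries (−0.14, 0.03 and −0.03). Its mean log2 fold change of −0.22 moved to −0.14 without knockout replicate 3 (adjusted p = 0.0489).

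The clock gene list was lower as well, and its members split by phase. Of 17 genes 14 were lower and 3 higher, with a median log2 fold change of −0.28 (camera, adjusted p = 0.000237; adjusted p = 0.726 with an estimated correlation and 0.0714 with fry). Adjusted over the list alone 6 genes passed, 5 lower and 1 higher. The lower ones were Per2 (50.3 ± 6.01 to 23.04 ± 4.08 CPM), Dbp (66.1 ± 9.18 to 35.9 ± 1.99 CPM), Hlf, Ciart and Per1 (SD, n = 3; edgeR adjusted p = 0.00475 over the list alone for Per2 and Dbp). The higher one was Arntl, which encodes the activator BMAL1 (8.72 ± 2.67 to 16.1 ± 0.869 CPM, SD, n = 3; edgeR adjusted p = 0.0309 over the list alone and 0.592 over all genes). Npas2, a partner of BMAL1, was at 3.17 ± 1.44 and 6.14 ± 0.353 CPM and Clock at 99.1 ± 10.9 and 104 ± 18.7 CPM (SD, n = 3). The authors' deposited table lists 5 genes of this list as lower at an adjusted p under 0.05.

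Among lists for other cell types, the mast cell and platelet list was higher in knockout nerve, with a median log2 fold change of 0.94 over 12 genes, 8 of them higher (camera, adjusted p = 0.00153; adjusted p = 0.747 with an estimated correlation). The platelet chemokine Ppbp passed over the list alone (1.06 ± 0.71 to 11.3 ± 6.57 CPM, SD, n = 3; edgeR adjusted p = 0.0343, and 0.328 over all genes). This call was lost without wildtype replicate 1 (mean log2 fold change 0.51, adjusted p = 0.0934) or knockout replicate 1 (0.47, adjusted p = 0.0562), against a mean of 0.84 with all libraries. The B cell list was also higher (12 of 19 genes higher, median 0.24, camera, adjusted p = 0.0487; adjusted p = 0.926 with an estimated correlation), and its call was lost without wildtype replicate 1 or 2 (adjusted p = 0.322 and 0.0841) and without knockout replicate 1 or 2 (adjusted p = 0.219 and 0.610). The mean log2 fold change of the B cell list, 0.35 with all libraries, was 0.20 and 0.35 without wildtype replicates 1 and 2, 0.14 and 0.0086 without knockout replicates 1 and 2, and 0.64 without wildtype replicate 3. Over all 19 alternatives, which include other filters and scalings, the B cell list passed in 10. The skeletal muscle list was lower (13 of 16 genes, median −0.96, camera, adjusted p = 0.0311; adjusted p = 0.926 with an estimated correlation). Its median stood at 1.32 above the wildtype mean in wildtype replicate 2 alone, and without that library the mean log2 fold change was −0.05 (adjusted p = 0.695), while without knockout replicate 1 it was −1.27 (adjusted p = 0.104), against −0.97 with all libraries. The list of stria vascularis, the secretory epithelium of the cochlear wall, was lower (17 of 19 genes, median −1.54, camera, adjusted p = 0.0495; adjusted p = 0.926 with an estimated correlation). Its median was 2.44 above the wildtype mean in wildtype replicate 3, and without that library the mean log2 fold change was 0.67 (adjusted p = 0.355), against −1.49 with all libraries and −3.35 without knockout replicate 2. The call was also lost without knockout replicate 1 (−1.24, adjusted p = 0.423) or 3 (−1.19, adjusted p = 0.230). One gene of that list passed over the list alone, the receptor tyrosine kinase Kit (77.8 ± 4.72 to 35.3 ± 4.65 CPM, SD, n = 3; edgeR adjusted p = 0.00212, and 0.0665 over all genes). All 5 sex-linked genes were lower (median −0.21, camera, adjusted p = 0.0311; adjusted p = 0.747 with an estimated correlation). Xist was at 0.497 ± 0.103 and 0.183 ± 0.153 CPM and the Y-linked Ddx3y at 132 ± 5.81 and 115 ± 9.81 CPM (SD, n = 3). A difference in sex would move Xist and the Y-linked genes of this list in opposite directions. Their joint fall, with Ddx3y abundant and Xist low in both groups, argues against a difference in sex between the groups. The sex-linked call was lost without knockout replicate 1 (mean log2 fold change −0.39, adjusted p = 0.143), wildtype replicate 2 (−0.44, adjusted p = 0.0841) or wildtype replicate 3 (−0.39, adjusted p = 0.0856), against a mean of −0.43 with all libraries.

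**Figure D2:**
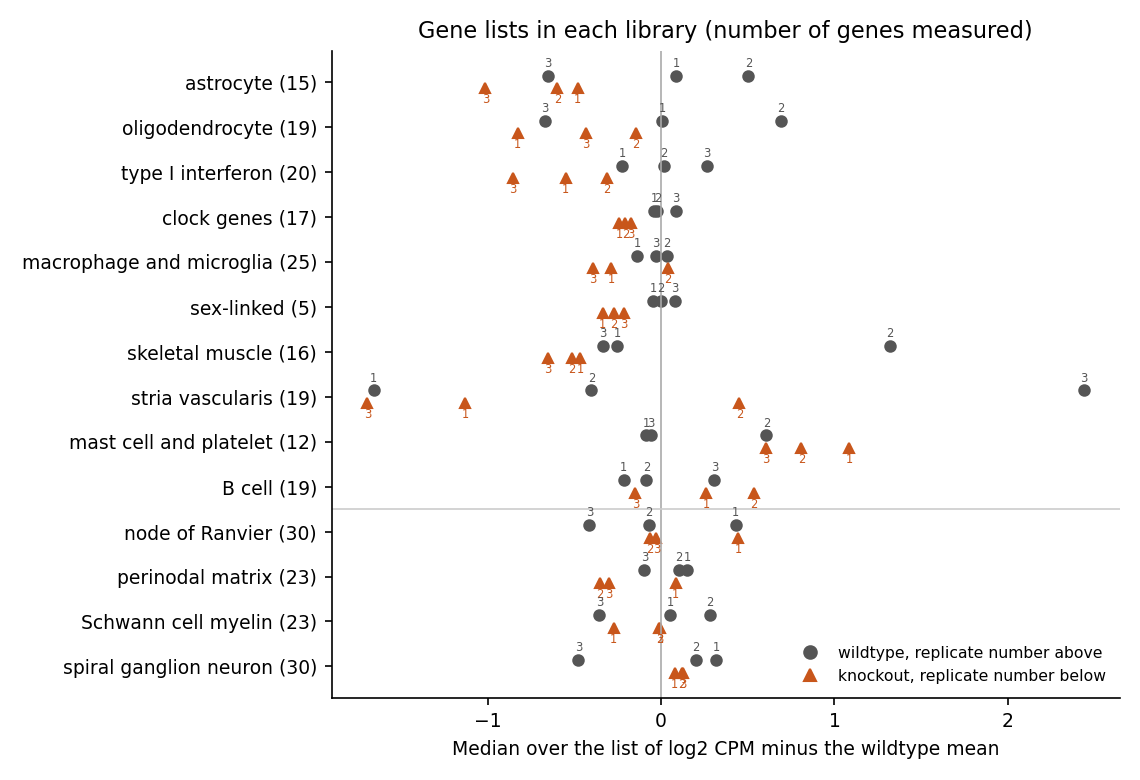
Median over each list of the log2 CPM of its genes relative to the wildtype mean, with a circle for each wildtype library and a triangle for each knockout library, numbered by replicate, and the 10 called lists above the line. The median of the astrocyte list is −0.65 in wildtype replicate 3, within the range of the knockout libraries (−1.01 to −0.48), and the stria vascularis median stands at 2.44 in wildtype replicate 3.

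The other 31 lists were not called with all libraries (adjusted p = 0.136 to 0.927), but 17 of them passed without some library. Means without a library are given here on the log2 scale, with the adjusted p in parentheses. With all libraries they were 0.93 for neutrophils, −0.36 for hair cells, 0.04 for ribosomal proteins, 0.07 for oxidative phosphorylation, −0.14 for cholesterol synthesis and −0.06 for bone. They were 0.01 for red cells, −0.02 for the cell cycle, 0.11 for synaptic vesicles, 0.21 for glial injury response, −0.11 for T cells and 0.20 for antigen presentation. The bone, cell cycle and T cell means thus turned sign in the fits in which they passed, and the hair cell mean turned to 0.27 without wildtype replicate 3, where it did not pass. Without knockout replicate 1 the neutrophil list had a mean log2 fold change of 1.32 (adjusted p = 2.29e-08) and the hair cell list −1.19 (0.0248). The ribosomal protein and oxidative phosphorylation lists had 0.18 and 0.20 there (both 0.002855). Without wildtype replicate 3 the means were 1.43 for neutrophils (0.0224), −0.25 for cholesterol synthesis (0.000236), and 0.21 for bone (0.00767). They were 0.73 for red cells (0.0159), 0.24 for the cell cycle (0.0131) and 0.13 for ribosomal proteins (0.0438). Cholesterol synthesis also passed without knockout replicate 2 (−0.18, 0.0458) or 3 (−0.17, 0.0289), and synaptic vesicles without wildtype replicate 1 (0.43, 0.000297). Hair cells (−0.61, 0.0460) and glial injury response (0.42, 0.0454) passed without wildtype replicate 2, and T cells (0.25, 0.0289) and antigen presentation (0.30, 0.0274) without knockout replicate 3. The 31 lists covered, besides those above, the proteases that cleave versican, genes near Vcan on chromosome 13, glial injury response, synaptic vesicles, hair cells, supporting cells, bone, osteoclasts, red cell, neutrophil and T cell lineages, connective tissue and basal lamina, endothelium and pericytes, complement and cytokines, antigen presentation, TGF-beta and BMP signalling, immediate early genes, heat shock, cholesterol synthesis, glycolysis, nuclear genes of oxidative phosphorylation, ribosomal proteins and the cell cycle. For 10 of the 31 the median, the mean and the test did not all have the same sign. Over the list alone, single members passed in edgeR in 4 of these lists besides the matrix list: Tspan2 of the Schwann cell myelin list (log2 fold change −1.10, SE 0.22), the osteoclast genes Oscar (−4.73, SE 0.72) and Dcstamp (2.94, SE 0.77), Sc5d of cholesterol synthesis (−0.86, SE 0.17) and Plk1 of the cell cycle (1.44, SE 0.29). None of these passed over all genes. The genes near Vcan had a median log2 fold change of 0.03 (24 genes, camera, adjusted p = 0.665), with none past the threshold, and Hapln1, which neighbours Vcan, was at 75.9 ± 13.8 and 71.6 ± 13.7 CPM (SD, n = 3).

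**Figure D3:**
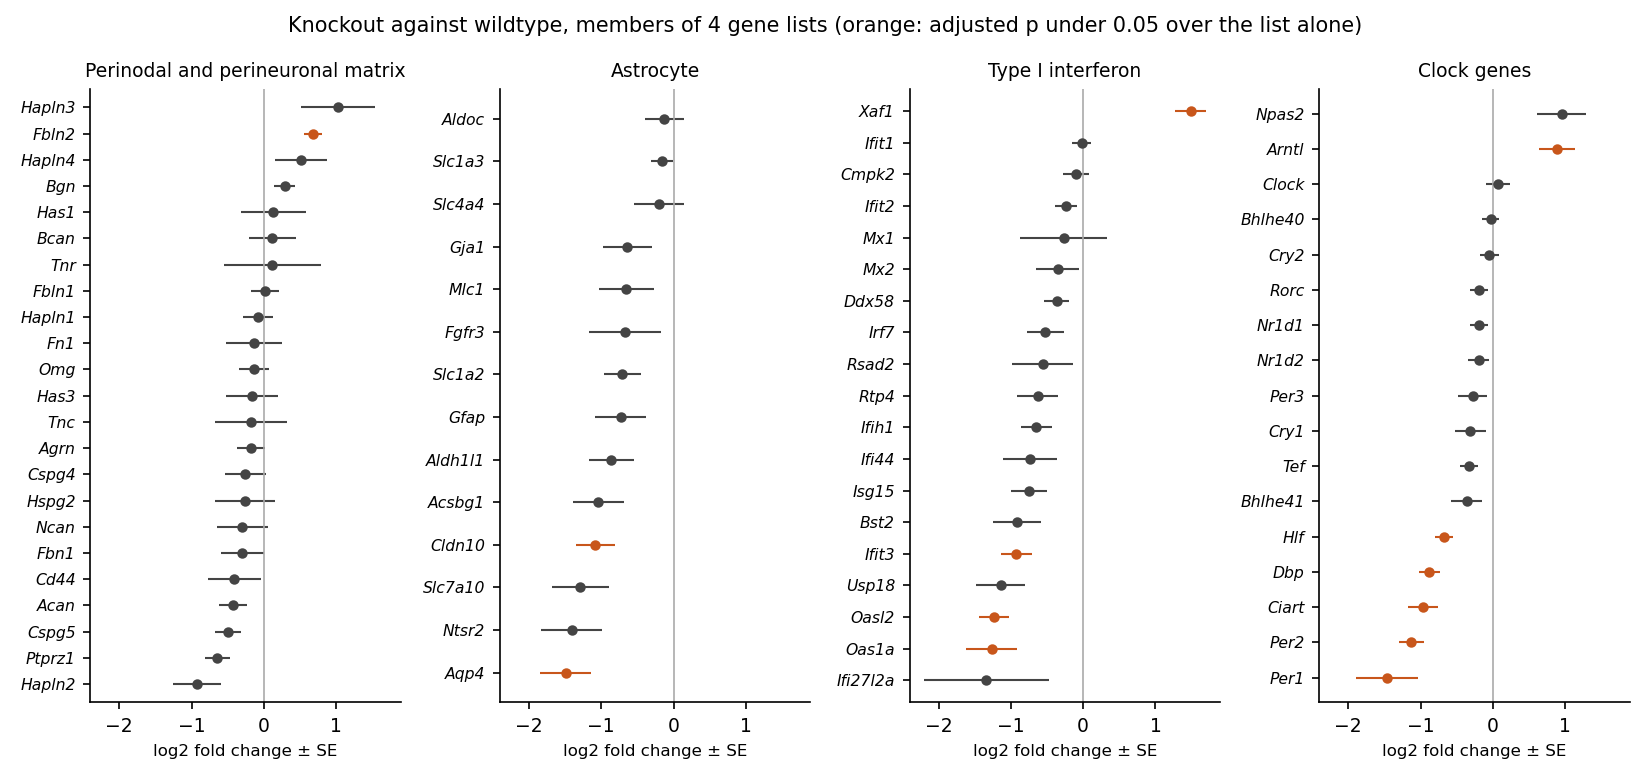
Log2 fold change of knockout against wildtype with its standard error for genes of the matrix, astrocyte, type I interferon and clock gene lists (not every measured gene is drawn), orange where the adjusted p over the list alone is under 0.05. The astrocyte genes drawn lie below 0, as do the interferon genes drawn apart from Xaf1, and Arntl and Npas2 lie above 0 while Per1 and Per2 lie below.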

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

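The alternatives with a correction for transcript length, a block for it, or surrogate variables were chosen after the data were seen. The 23 changed genes became between 21 and 30 under other scalings, filters, limma-voom (22, of which 18 shared) and the offset for transcript length, and 18 with a block for the length trend, 15 of them shared. Outside 1.5 times were 3 with the replicate block, 8 with 1 surrogate variable and 870 with 2, 252 with DESeq2, 41 at an adjusted p under 0.1 and 9 under 0.01, and leaving out a library gave 3 to 14. With 2 surrogate variables another split of the samples gave 5382, more than the real split. In the simulation 32.4% of DESeq2 calls and 9.74% of edgeR calls were false. It drew genes independently with edgeR's own dispersions, so it cannot settle why DESeq2 called more genes. The loss of calls without a library goes with fewer samples, and the cause of the other shifts was not tested. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at 0.536, 0.337 and −0.131 over 13542 genes, and not every sample correlated best with its own number. The numbers and the block came from the titles, and the knockout descriptions number replicates 2 and 3 as 3 and 4, by which wildtype replicate 3 would pair with knockout replicate 2 (0.244). All 15 named genes and Vcan kept their direction in all 19 alternatives. The groups did not overlap for any of them, so leaving out a library could hardly turn the direction. The log2 fold change of Vcan ranged from −1.60 to −1.02 (adjusted p = 0.0329 to 0.9999) and passed the threshold in 2, DESeq2 (−1.20, adjusted p = 0.0342) and 2 surrogate variables (−1.25, adjusted p = 0.0329). Of the 10 called lists 0 remained with an estimated correlation and 0 with fry, and leaving out a library gave 8 to 16 called lists, 16 without wildtype replicate 3. Of the 10 called lists 4 were kept without knockout replicate 1 and 6 without wildtype replicate 2, and 8 or 9 without each other library. The astrocyte, interferon, clock and macrophage lists passed in 17 of 19 alternatives, all but those 2 tests. The stria vascularis list reversed without wildtype replicate 3 (0.67) and with 1 surrogate variable (0.272), and its mean ranged from −3.354 to 0.673 over the fits that left out a library. The node of Ranvier list was called with the block for the length trend (0.175, adjusted p = 0.0157). Of 777 list values under alternatives, 71 changed direction while uncalled in both fits. Scalings moved the median of all genes by less than 0.02 on the log2 scale. Depth limits genes near 3 counts per group, such as Gbp2b in wildtype nerve.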

Other observations

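Except for those tested with the splits of the samples and the clock genes, explanations in this part were written after the result was seen. The DESeq2 fit, the list tests and the fits that left out a library had been planned. DESeq2 called a run of neighbouring protocadherin genes on chromosome 18, which encode neuronal adhesion molecules. Pcdhb5 was at 2.98 ± 0.428 and 6.06 ± 0.275 CPM, Pcdhb6 at 1.77 ± 0.338 and 4.39 ± 0.526, Pcdhb7 at 4.08 ± 0.881 and 8.47 ± 0.873 and Pcdhb8 at 1.97 ± 0.434 and 4.03 ± 0.542 (wildtype and knockout, SD, n = 3). Their neighbour Pcdhb9, not called by DESeq2, was at 9.54 ± 1.17 and 6.07 ± 0.531 CPM. None of the 5 passed in edgeR. The named genes fell outside the naming rule and were chosen after their values were seen. In the neutrophil list (adjusted p = 0.266), the lactoferrin gene Ltf was at 5.87 ± 5.76 and 64.5 ± 55.9 CPM (SD, n = 3), and the list's median relative to the wildtype mean ranged from −1.79 in knockout replicate 1 to 1.56 in knockout replicate 2.

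The large changes lay at genes spread over 13 chromosomes. Reads shared with near-copies of a gene are a candidate explanation for part of them. Of the 22 changed genes with a sequence, 45.45% (10 genes, Eno1b, Rpl29, Vmn2r29 and Acp1 among them) had at least 10% of their 50-base stretches in a gene at another locus. Sets drawn to match expression had 5.19% on average (permutation p = 1e-04, the smallest that 10000 draws can give). The draws did not match gene class, and the 10 include the predicted genes or pseudogenes Gm15446, Gm5801, BC002163, Gm13152 and Gm13157. The permutation p therefore cannot tell sharing from gene class. Sharing makes a group difference only where the groups' sequences or expression of the copies differ, and it leaves the other 12, such as Nnt and Pttg1 with 0%, unaddressed. A genetic background of the knockout animals that differs from C57BL/6J, the strain known to carry a multi-exon deletion in Nnt, may also contribute and stays open: 41.2% of the 250 genes with the smallest p lay within 1 Mb of another, above the 95th percentile of random draws (37.2%) and above the 9 other splits (25.2% to 39.6%), but without neighbours of like symbol it was 36.4%, no higher than the 95th percentile (36.42%) or the highest other split (36.4%). Preparation of the groups' libraries in separate series cannot be told apart from genotype, since 0 libraries were numbered among those of the other group, and versican deficiency itself stays open as untested. Of the 10 splits of the 6 samples, which are too few for a share under 0.05, 2 gave at least 23 changed genes, counting the real one. The other, wildtype replicates 1 and 3 with knockout replicate 1 against the rest, gave 915, which points to a structure of the samples. It follows the sign of each library's trend with transcript length. That trend was near 0 in wildtype replicate 3 (r = 0.06), against 0.33 in wildtype replicate 1 and 0.42 in knockout replicate 1. With a block for that trend 18 genes passed.

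The astrocyte and oligodendrocyte lists were lower together in knockout nerve. Without wildtype replicate 2 the astrocyte list kept its call (camera with the preset correlation, adjusted p = 0.001024). Its mean log2 fold change was then −0.57, against −0.77 with all libraries, so the lower mean did not rest on that library alone. The kept call adds little, since with all libraries it was lost under an estimated correlation (adjusted p = 0.747). The oligodendrocyte list lost its call without wildtype replicate 2 (camera with the preset correlation, adjusted p = 0.0841). Less central nerve tissue in the knockout pieces may account for both: their mean log2 fold changes differed by 0.1919 (95% interval −0.0755 to 0.468 over resampled genes, which does not cover the spread between animals), and by 0.433 without knockout replicate 1, 0.363 without wildtype replicate 2 and 0.0535 without knockout replicate 3, so how alike they moved is not secure. The abundant Gfap was at 371 ± 138 CPM in wildtype and 223 ± 69.5 CPM in knockout nerve (SD, n = 3). A smaller central glial population in versican-deficient nerve was not tested apart, and for the lists, 9 of the 10 splits, too few for a share under 0.05, gave at least as many calls as the real 10, and the highest other gave 18.

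The clock list moved by phase. A different time of day at collection is a candidate explanation: Arntl, Clock and Npas2, which peak opposite to the Per, Dbp and Nr1d genes, had a mean log2 fold change of 0.6375 (SE 0.283 over 3 genes), and 9 genes of the opposite phase a mean of −0.68 (SE 0.15), all 9 lower. The labels give no time of collection, and an effect of genotype on the clock was not tested.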
